A study of Mus musculus with 5 samples.

How the data were processed

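RNA of 5 mouse livers at embryonic day 18.5 was measured by sequencing of poly(A)-selected libraries, 3 in the 4N group and 2 in the WT group, as the titles and genotype labels assign them. The series design text also names heart and a second stage, which were not analysed here. Library preparation used poly-T beads and random hexamer priming, per the labels' protocols. The genome build was GRCm39, per the submitters' processing notes, and the aligner and counting tool are not given in the sources used here. The authors deposited 1 comparison table with no values of single libraries. Its mean signal is the mean normalized count of a gene over all libraries, per the file headers. Its log2 fold changes and their standard errors are on the log2 scale, per the file headers. Its Wald statistic is a score equal to the log2 fold change over its standard error, per the file headers and a recomputation. Its p-values and adjusted p-values were made by the authors, and the column names match those of DESeq2, per the file headers. Checked on the values, the p-values were the 2-sided normal tail of the statistic and the adjusted ones the Benjamini-Hochberg adjustment over the 23022 genes listed, with 0 missing. Genes were matched by symbol, and 22299 of them had a chromosome and gene type in GENCODE M21, which describes another build and was used for chromosome names and gene types only.

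The design written before the data were examined assumed raw counts and planned quasi-likelihood tests on them. Because the file held a comparison table, none of the planned tests could be run, and the similarity of the libraries was not analysed here. In their place, the authors' adjusted p under 0.05 defined the calls, and 46 gene lists fixed before the data were examined were tested with cameraPR of limma on the Wald statistics (preset inter-gene correlation 0.01, 2-sided, Benjamini-Hochberg over the lists with at least 5 members). The correlation could not be estimated without values of single libraries, so a preset of 0.05 was tried instead, and list members called after adjustment over the list alone are given beside the counts. Chromosomes were tested in the same way. The median of each chromosome's genes with a mean of at least 1000 was given a 95% interval from 2000 bootstrap resamples. Permutation tests of list medians used 100000 permutations.

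The sign of the fold changes was settled from genes at the fitting floor of 0.5 counts, whose standard error has a lower limit set by the number of libraries in the empty group, and the check was tested on simulated data. Named genes followed a rule fixed beforehand. It took Hhex, Xist and 4 Y-linked genes, the 10 largest rises and falls among called genes with a mean of at least 0.0005% of the summed means and a symbol that is no clone or predicted model, and in each list the called members with the smallest adjusted p, up to 4 where calls went 1 way and up to 3 per direction where they went both ways, or the 2 most abundant members where none was called. It always took Alb, Afp, Hbb-bs, Cdkn1a, H19, Igf2 and Dlk1. That share stood in for the planned minimum on values per library, and the part of the rule asking that groups do not overlap could not be applied. No fold is given for genes with no reads in one group. One gene that the rule named is not reported here. In a simulation with the table's standard errors for the comparison of 4N with WT liver over 23022 genes, 200 genes were changed. At a log2 change of 2, 49.0% of 100 changed genes were recovered, and 34 of the 34 with a mean of at least 1000. At a log2 change of 1, 28.0% of 100 were recovered, and 21 of 37 with a mean of at least 1000. Over both sizes together, 3 of the 80 calls were false. The errors were drawn as normal with those standard errors, so this share does not test whether the standard errors are right. In simulated statistics with 1 shifted list of 46, that list was called and 0 others. These statistics were drawn independently for each gene, so they do not test how inter-gene correlation affects the list p-values.

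Alternatives, all chosen after the data were seen, were a minimum mean of 50, a test against a 1.5-fold change, an adjusted p under 0.01, a t reference with 3 degrees of freedom, recentring on genes with a mean of at least 10000 or on the secreted plasma proteins, leaving out genes at the floor and, for lists, the log2 fold change as statistic, ranks, another preset correlation and 10000 random lists matched on mean. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.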

Results

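Livers of E18.5 mouse embryos were profiled by RNA sequencing of poly(A)-selected RNA in 5 libraries. The 4N group held 3 libraries, from embryos whose blastocysts lacked Hhex, a homeobox gene needed for liver formation, and had received tetraploid embryonic stem cells carrying a red fluorescent marker. The WT group held 2 libraries from unmanipulated embryos of the same day. The 2 groups thus differed in ploidy, in the origin of the liver cells, in the Hhex genotype of the host embryo and in its manipulation at once. The labels do not say whether the libraries of a group came from separate litters. The p-values of the authors' test therefore measure the spread between these samples. Tests of lists, families, chromosomes and pseudogenes, and the bootstrap intervals, take genes as the units. They do not measure the spread between livers. The data used here were the authors' comparison of the 2 groups, with 23022 genes by symbol, and values of single libraries were not analysed here. The depth of each library is therefore unknown, and the sum of the mean normalized counts over all genes, about 78100000, is the only measure of it. Albumin took 7.94% of that sum, the mitochondrially encoded genes 3.25% and the 50 most abundant genes 34.2%. The median standard error of a log2 fold change was 0.24 for the 8656 genes with a mean of at least 1000 normalized counts, and 1.62 for the 7792 genes with a mean under 50.

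Hhex, the gene missing from the host embryos, had transcripts in the 4N livers and did not pass the test. The authors' deposited table gave it a mean of 5894 normalized counts over all libraries and a log2 fold change of 0.55 (SE 0.33, adjusted p = 0.29). After recentring on the secreted plasma proteins the value was 1.03 (adjusted p = 0.0084), past the threshold, against adjusted p-values of 0.24 to 1 under the other alternatives. A liver lacking Hhex transcripts in the 4N group was thus not seen at the level of group means, although single libraries could not be examined. Albumin, the main plasma protein of hepatocytes, did not pass the test either (log2 fold change 0.01, SE 0.22, in the authors' deposited table). All fold changes are given as 4N against WT. The table does not name its numerator, and this direction was settled from genes with no reads in one group. Of these, 606 genes had positive and 247 negative values, and 12 of the negative ones had a standard error below 1.44, the smallest possible if the empty group had held 2 libraries. The empty group behind negative values was therefore the one with 3 libraries, the 4N group.

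The question behind the main comparison was how a liver built from tetraploid cells differs from a diploid one in gene expression. The 4N livers had lower transcripts of drug-metabolizing enzymes and of other genes of the mature hepatocyte, and higher transcripts of globins and of lipid synthesis enzymes. Of 23022 genes, 1828 were higher and 1705 lower in 4N liver at an adjusted p under 0.05 by the authors' Wald test. The counts were 521 and 588 in a test against a 1.5-fold change, and 0 and 0 with a t reference of 3 degrees of freedom in place of the normal one (2513 genes at an unadjusted p under 0.05), both chosen after the data were seen. Of the calls by the authors' test, 1195 rose and 1230 fell by at least 2-fold. Among the 10 largest rises of the named-gene rule, the authors' deposited table gave log2 fold changes of 10.27 for the embryonic globin Hbb-y (adjusted p = 4.1e-10) and 7.07 for the embryonic globin Hba-x (SE 1.60). Serpina6, which encodes corticosteroid-binding globulin, rose by 6.60 (SE 0.37, adjusted p = 4.0e-66) in the authors' deposited table. The others were the peptide transporter Slc15a2 (8.52, SE 2.58), the steroid dehydrogenase Hsd3b6 (7.01, SE 1.07), the kinase subunit Camk2b (6.45), the purine nucleoside phosphorylase Pnp2 (6.08), the lipase-related Pnliprp1 (5.97), the hexokinase Hkdc1 (5.14) and the antitrypsin copy Serpina1e (32.0-fold, SE 1.54 on the log2 scale), in the authors' deposited table. The 95% intervals were wide for Slc15a2 (3.47 to 13.58) and Serpina1e (1.99 to 8.02), as computed from the standard errors of the authors' deposited table. Both genes had a mean of at least 1000, where the median standard error was 0.24, so their libraries may differ within a group. Reads of Serpina1e can also be shared with its close copies, which makes its value uncertain. The 10 largest falls were led by Cyp1a2, a xenobiotic-metabolizing cytochrome, at -11.42 (SE 1.63, adjusted p = 1.6e-10) in the authors' deposited table. They included the lipoprotein gene Apoa4 at -10.50 (SE 1.62) and Pck1, the rate-limiting enzyme of gluconeogenesis, at -9.10 (SE 0.68, adjusted p = 1.2e-37), in the authors' deposited table. The authors' deposited table also placed Cyp2c50 (-10.77), Ces1b (-10.11), Cyp2b10 (-9.63), Inmt (-8.12), Cyp3a25 (-7.33), Cyp4a14 (-6.97) and Mug1 (-6.86) among them. For Cyp1a2, Cyp2c50, Cyp2b10 and Ces1b the fitted 4N mean was 1.30, 1.60, 1.61 and 2.34 normalized counts, and for Hbb-y the fitted WT mean was 1.05, so these folds rest on few reads in the lower group. Hsd3b6 (SE 1.07), Cyp1a2 (SE 1.63), Apoa4 (SE 1.62) and Ces1b (SE 2.33) also had a mean of at least 1000, so their libraries may differ within a group too. The 95% interval for Hbb-y, computed from its standard error in the authors' deposited table, was 7.33 to 13.20, and that for Cyp1a2 was -14.62 to -8.23. Recentring on the secreted plasma proteins, a choice made after the data were seen, moved all log2 fold changes up by 0.48 and gave 5513 higher and 944 lower genes, 85.4% against 51.7% higher.

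**Figure D1:**
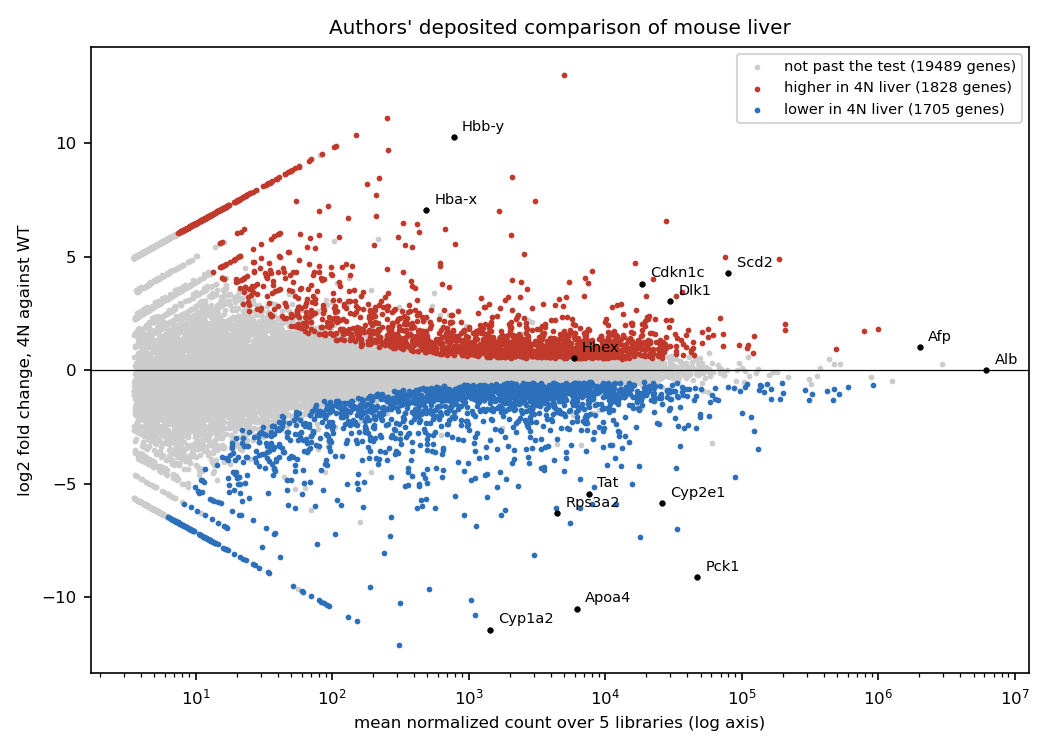
Log2 fold change of 4N against WT liver (vertical axis) against the mean normalized count over all libraries (horizontal axis, log scale) for each gene of the authors' deposited table, with 1828 genes higher in red and 1705 lower in blue. Straight diagonal lines of points at low means are genes with no reads in one group.

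Lists of genes of the mature hepatocyte were lower, and the maturation and cytochrome P450 lists had the lowest medians of the 46 lists. Of 25 measured genes that rise in hepatocytes after birth, 18 fell, 2 rose and 5 did not pass the test (19 and 2 adjusted over the list alone), with a median log2 fold change of -2.88 (camera adjusted p = 3.4e-41). The authors' deposited table gave -5.43 (SE 0.22) for Tat, a tyrosine-degrading enzyme, -5.67 (SE 0.36) for Tdo2, which opens tryptophan catabolism, and -5.87 (SE 0.41) for the ethanol-oxidizing Cyp2e1. The bile acid enzyme Cyp7a1 (0.80, SE 0.24) and the alcohol dehydrogenase Adh1 (1.08, SE 0.32) were the exceptions that rose in the authors' deposited table. Of 20 cytochrome P450 and conjugating enzymes, 16 fell and 1 rose (16 and 2 adjusted over the list alone), with a median of -2.91 (adjusted p = 4.6e-30). Of 22 urea cycle and amino acid catabolism genes, 18 fell and 0 rose (18 and 0 adjusted over the list alone), with a median of -1.20 (adjusted p = 2.1e-24), and Agxt, which detoxifies glyoxylate, stood at -4.21 (SE 0.29) in the authors' deposited table. Of 21 PPAR alpha targets and fatty acid oxidation genes, 16 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.90 (adjusted p = 5.4e-21), and Cpt1a, the gate of mitochondrial fatty acid import, fell by 2.33 (SE 0.26) in the authors' deposited table. Erythroid markers moved the other way in the same comparison, with a median of 1.56. Bile acid synthesis and transport genes fell in 10 of 14 cases and rose in 1 (11 and 1 adjusted over the list alone), with a median of -1.25 (adjusted p = 4.6e-16). Most of these hepatocyte lists share members, so their results are not independent. Of the measured genes, 17 of 25 in the maturation list also stood in another list. So did 6 of 20 in the cytochrome P450 list, 5 of 22 in the urea cycle list and 4 of 14 in the bile acid list. Fgf21, a fasting hormone of the liver singled out after its values were seen, was called lower and had no reads in the 4N group according to its place at the fitting floor of the authors' deposited table.

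Lists of secreted and defence proteins were lower too. Of 27 secreted plasma protein genes, 13 fell, 1 rose and 13 did not pass (14 and 1 adjusted over the list alone), with a median of -0.48 (adjusted p = 1.4e-05), a median that recentring on this list sets to 0. The heme carrier Hpx (-2.67, SE 0.20) and Fetub (-2.36, SE 0.27) fell in the authors' deposited table. Complement and coagulation genes fell in 12 of 24 cases and rose in 2 (13 and 2 adjusted over the list alone; median -0.67, adjusted p = 1.3e-05). Acute phase genes fell in 8 of 17 cases and rose in 1 (12 and 1 adjusted over the list alone; median -2.41, adjusted p = 2.8e-07). Of 20 interferon response genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.75, adjusted p = 3.3e-04), among them the nucleic acid sensor Zbp1 at -3.03 (SE 0.35) in the authors' deposited table. Of 21 hepatocyte transcription factors, 5 fell and 2 rose (6 and 2 adjusted over the list alone; median -0.16, adjusted p = 0.037, and adjusted p = 0.13 with a preset correlation of 0.05). The xenobiotic receptor Nr1i3 (-4.36, SE 0.41) and the bile acid sensor target Nr0b2 (-4.08, SE 0.42) fell in the authors' deposited table. Recentring on the secreted proteins turned the median of the transcription factors to 0.31 and ended that list's call (adjusted p = 0.30).

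The fetal hepatoblast list was higher by camera, although most of its members did not pass. Of 17 fetal hepatoblast genes, 6 rose, 1 fell and 10 did not pass (7 and 1 adjusted over the list alone; median 0.58, adjusted p = 2.3e-04). In the authors' deposited table, alpha-fetoprotein (Afp) rose by 1.03 (SE 0.26, adjusted p = 9.6e-04), the hepatoblast surface protein Dlk1 by 3.04 (SE 0.23, adjusted p = 2.3e-36) and the RNA-binding protein gene Igf2bp2 by 2.37 (SE 0.27). Of 33 imprinted genes, 12 rose and 2 fell (12 and 4 adjusted over the list alone; median 0.45, adjusted p = 2.9e-06). Besides Dlk1, its imprinted neighbour Rian (2.37, SE 0.21) rose in the authors' deposited table, as did Cdkn1c, a growth-restraining cell cycle inhibitor (3.82, SE 0.30). H19 (-0.29, SE 0.19) and Igf2 (0.39, SE 0.30) did not pass the test in the authors' deposited table. Dlk1, H19, Igf2 and Peg3 were members of both the fetal hepatoblast and the imprinted list.

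Lists of lipid synthesis and glycolysis genes were higher. Of 17 fatty acid synthesis genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone; median 1.46, adjusted p = 1.3e-16). The desaturases Scd1 and Scd2, which make monounsaturated fatty acids, rose by 4.71 (SE 0.22) and 4.28 (SE 0.19) in the authors' deposited table. Of 23 cholesterol synthesis genes, 17 rose and 1 fell (19 and 1 adjusted over the list alone; median 0.94, adjusted p = 4.6e-16), with Lss, which closes the sterol ring system, at 2.08 (SE 0.21) in the authors' deposited table. Of 16 glycolysis genes, 11 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.85, adjusted p = 2.8e-10). Erythroid markers rose in the same comparison, with a median of 1.56. Hypoxia targets rose in 8 of 16 cases and fell in 1 (11 and 2 adjusted over the list alone; median 0.82, adjusted p = 1.3e-08). The glucose transporter Slc2a1 (2.66, SE 0.31) and the stress-responsive Ndrg1 (2.91, SE 0.26) rose, whereas Epo, the erythropoietin gene, fell (-3.87, SE 0.99), all in the authors' deposited table. Slc2a1, Ldha and Pfkfb3 were members of both the glycolysis and the hypoxia list. Gluconeogenesis and glycogen genes split, with 4 higher and 5 lower of 15 (4 and 5 adjusted over the list alone; median 0.10, mean -0.52, adjusted p = 0.80). Iron and heme handling genes did not move as a list, with 2 higher and 4 lower of 18 (3 and 4 adjusted over the list alone; median 0.17, adjusted p = 0.46), although the iron hormone Hamp fell (-2.71, SE 0.44) and its close copy Hamp2 rose (3.88, SE 0.76) in the authors' deposited table. Reads of such copies can be shared, which makes both values uncertain.

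**Figure D2:**
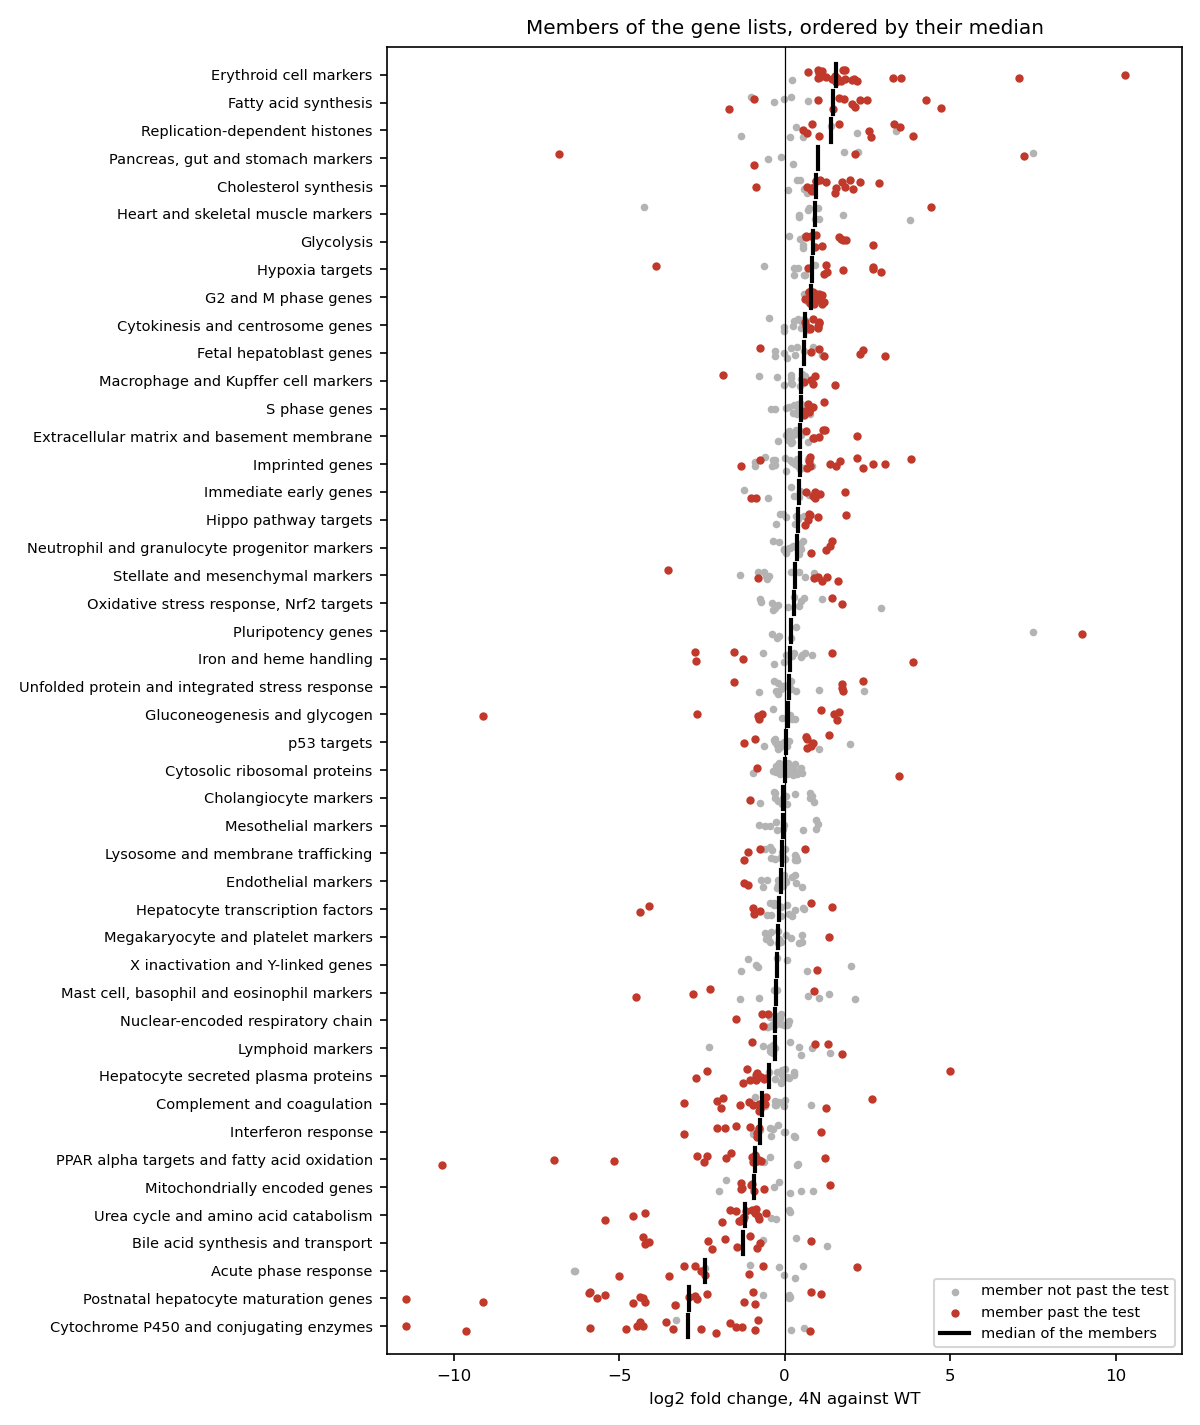
Log2 fold change of 4N against WT liver (horizontal axis) for the measured members of each of the 46 gene lists (vertical axis), ordered by list median. Red points passed the authors' test, grey points did not and black bars are medians, which run from -2.91 for cytochrome P450 and conjugating enzymes to 1.56 for erythroid markers.

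Red blood cell genes rose almost without exception. Of 24 erythroid markers, 23 rose and 0 fell (23 and 0 adjusted over the list alone; median 1.56, adjusted p = 2.6e-30), and only the transferrin receptor gene Tfrc did not pass (0.23, SE 0.22, in the authors' deposited table). The adult globin Hbb-bs rose by 1.71 (SE 0.20), and Bpgm, which makes the red cell regulator of oxygen release, by 2.08 (SE 0.24), in the authors' deposited table. Neutrophil and granulocyte progenitor markers rose in 4 of 18 cases and fell in 0 (4 and 0 adjusted over the list alone; median 0.38, adjusted p = 0.011, and adjusted p = 0.054 with a preset correlation of 0.05). Macrophage and Kupffer cell markers had 5 higher and 1 lower of 18 (6 and 2 adjusted over the list alone; median 0.49, adjusted p = 0.058). Mast cell, basophil and eosinophil markers had 1 higher and 3 lower of 12 (2 and 4 adjusted over the list alone; median -0.27, adjusted p = 0.023, and adjusted p = 0.062 with a preset correlation of 0.05), and after recentring on the secreted proteins their median turned to 0.21 while the camera test still called the list lower (adjusted p = 0.012). Hdc, the histamine-forming enzyme of basophils and mast cells, fell by 4.49 (SE 0.31) in the authors' deposited table. Megakaryocyte markers had 1 higher and 0 lower of 16 (1 and 0 adjusted over the list alone; median -0.19, adjusted p = 0.87), and lymphoid markers 3 higher and 1 lower of 17 (3 and 1 adjusted over the list alone; median -0.30, mean 0.06, camera direction higher, adjusted p = 0.59).

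Markers of other resident cells moved little as lists. Endothelial markers had 0 higher and 2 lower of 17 (0 and 2 adjusted over the list alone; median -0.10, adjusted p = 0.43), and cholangiocyte markers 0 higher and 1 lower of 15 (0 and 1 adjusted over the list alone; median -0.06, adjusted p = 0.94). Stellate and mesenchymal markers had 5 higher and 2 lower of 18 (7 and 3 adjusted over the list alone; median 0.31, adjusted p = 0.56), and mesothelial markers 0 called of 11 (0 adjusted over the list alone; median -0.06, adjusted p = 0.94). Extracellular matrix and basement membrane genes rose in 7 of 19 cases (7 and 0 adjusted over the list alone; median 0.45, adjusted p = 0.0017). Of lists whose members are mostly silent in liver, pancreas, gut and stomach markers had 2 higher and 2 lower of 10 measured (2 and 2 adjusted over the list alone; adjusted p = 0.38), and heart and skeletal muscle markers 1 higher and 0 lower of 11 (1 and 0 adjusted over the list alone; adjusted p = 0.30). Pluripotency genes had 1 higher of 7 (1 and 0 adjusted over the list alone; adjusted p = 0.41), the nuclear receptor gene Esrrb, which had no reads in the WT group.

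Each of the 3 cell cycle lists was higher. Of 25 G2 and M phase genes, 23 rose and 0 fell (25 and 0 adjusted over the list alone; median 0.81, adjusted p = 2.8e-13), and cyclin A2 (Ccna2) stood at 1.12 (SE 0.21) and the kinetochore gene Cenpf at 1.18 (SE 0.22) in the authors' deposited table. Erythroid markers, some of which belong to dividing precursors, rose alongside with a median of 1.56. S phase genes rose in 8 of 25 cases (11 and 0 adjusted over the list alone; median 0.48, adjusted p = 2.3e-04), and cytokinesis and centrosome genes in 10 of 21 (13 and 0 adjusted over the list alone; median 0.62, adjusted p = 2.0e-05). Histone genes rose in 10 of 17 cases (12 and 0 adjusted over the list alone; median 1.40, adjusted p = 5.1e-06); replication-dependent histone transcripts largely lack poly(A) tails, so their level also depends on the selection step. Hippo pathway targets rose in 6 of 15 cases (7 and 0 adjusted over the list alone; median 0.41, adjusted p = 0.011). Of 23 p53 targets, 6 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.04, adjusted p = 0.52), and the cell cycle inhibitor Cdkn1a stood at -0.29 (SE 0.39) without passing in the authors' deposited table.

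Of the stress and housekeeping lists, those of the mitochondria were lower and the others did not pass, while erythroid markers had a median of 1.56 in the same comparison. Immediate early genes had 6 higher and 2 lower of 16 (6 and 2 adjusted over the list alone; median 0.44, adjusted p = 0.058). Unfolded protein and integrated stress response genes had 4 higher and 1 lower of 21 (4 and 1 adjusted over the list alone; median 0.14, adjusted p = 0.084), among them Psat1, a serine synthesis enzyme, at 2.37 (SE 0.30) in the authors' deposited table. Nrf2 targets had 2 higher and 0 lower of 15 (2 and 0 adjusted over the list alone; median 0.29, adjusted p = 0.18), and lysosomal genes 1 higher and 3 lower of 19 (1 and 3 adjusted over the list alone; median -0.07, adjusted p = 0.28). Cytosolic ribosomal protein genes had 1 higher and 1 lower of 37 (1 and 1 adjusted over the list alone; median 0.02, adjusted p = 0.43); the exception that rose, Rps2 (3.46, SE 0.23 in the authors' deposited table), has near-identical pseudogene copies, which makes its value uncertain. Mitochondrially encoded genes had 1 higher and 7 lower of 15 (1 and 8 adjusted over the list alone; median -0.92, adjusted p = 0.018, and adjusted p = 0.062 with a preset correlation of 0.05). Nuclear-encoded respiratory chain genes had 0 higher and 4 lower of 25 (0 and 4 adjusted over the list alone; median -0.29, adjusted p = 0.0077, and adjusted p = 0.056 with a preset correlation of 0.05), with a median of 0.19 after recentring on the secreted proteins. In all, 14 lists were higher and 13 lower of 46 by camera on the Wald statistics. With the log2 fold change itself as the statistic, 5 lists passed as higher (erythroid, fatty acid synthesis, cholesterol synthesis, histones and pluripotency) and 6 as lower (maturation, cytochrome P450, urea cycle, PPAR alpha, bile acid and acute phase), and the other calls were lost. The pluripotency list had a mean of 2.32 against a median of 0.18, with 2 of its 7 members at the fitting floor, where folds are uncertain. With ranks, the hepatocyte transcription factor (adjusted p = 0.21) and mast cell (adjusted p = 0.50) lists lost theirs, and the macrophage (adjusted p = 0.012) and immediate early (adjusted p = 0.037) lists passed as higher. Against matched random lists, the same lists were lost (adjusted p = 0.24 and 0.37) and gained (adjusted p = 0.0048 and 0.013), and the pancreas, gut and stomach list passed as higher (adjusted p = 0.027).

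The chromosomes were compared to ask whether the 4N livers had lost or gained whole chromosomes. No chromosome stood apart among 21 by the camera test of limma (smallest adjusted p = 0.99). For genes with a mean of at least 1000, the autosomal medians lay between -0.08 and 0.10, with bootstrap intervals from -0.15 to 0.15. Loss of 1 of 4 copies from all cells of all 4N libraries would give -0.42 if expression followed copy number, and gain of 1 copy would give 0.32, and these intervals exclude both. The same loss in 1 of 3 libraries would give -0.13, which the interval of chromosome 13 (-0.15 to -0.03) includes, and the gain would give 0.12, which those of chromosomes 7 (0.04 to 0.13), 15 (0.05 to 0.15) and 17 (0.03 to 0.12) include. The intervals of 6 autosomes lay above 0 and that of 1 below it. A loss or gain in only part of the cells would give smaller shifts, which these intervals need not exclude. The share of host cells in the 4N livers was not examined. The X inactivation and Y-linked list had 1 higher and 0 lower of 9 (1 and 0 adjusted over the list alone; adjusted p = 0.50), and the member that rose was the X-linked demethylase Kdm5c (0.99, SE 0.21, in the authors' deposited table). The Y-linked genes Ddx3y (-0.87), Uty (-1.11), Kdm5d (-0.82) and Eif2s3y (-1.31) did not pass in the authors' deposited table. Their standard errors of 2.71 to 2.91 compare with a median of 0.24 for 4745 other genes of similar mean, of which 0 had one as large. Y-linked transcripts thus appear to have differed strongly between libraries of a group. The sex of the embryos was not examined, and whether it bears on the Kdm5c value was not tested. Xist was not analysed here.

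**Figure D3:**
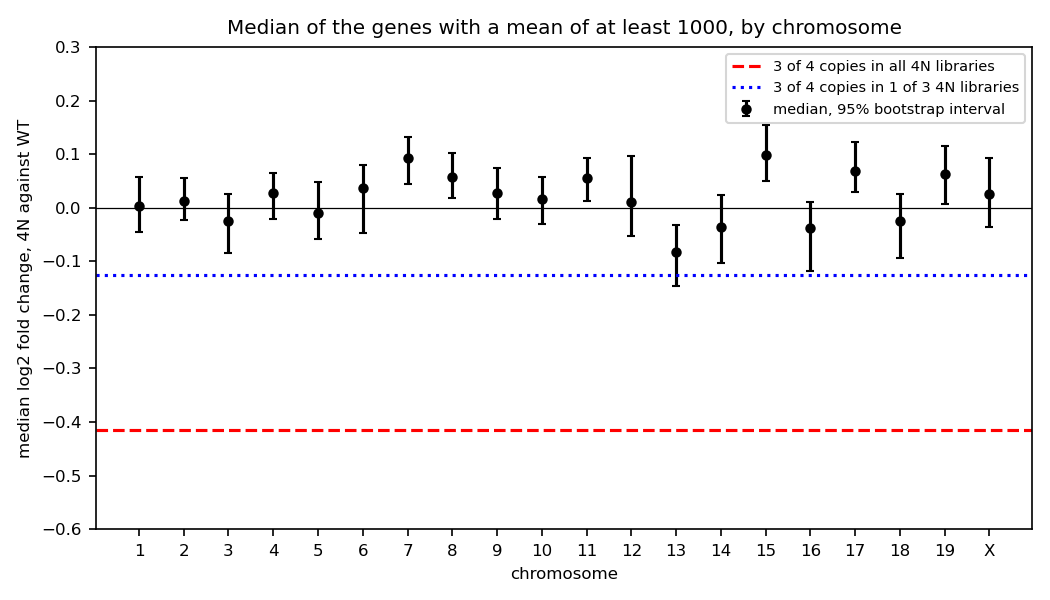
Median log2 fold change of 4N against WT liver (vertical axis) of the genes with a mean of at least 1000 normalized counts on each chromosome (horizontal axis), with 95% bootstrap intervals. The autosomal medians lie between -0.08 and 0.10, above the dashed line at -0.42 for 3 of 4 copies in all 4N libraries.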

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

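All alternatives here were chosen after the data were seen, because the planned ones (other normalizations, count tests, filters on counts, estimated correlation, self-contained list tests, each library left out in turn) need values of single libraries and were not run. No paired analysis was possible because the replicate numbers run on across the groups and the table holds no single libraries. The counts of higher and lower genes were within 1.5 times of 1828 and 1705 with a minimum mean of 50, without floor genes and after recentring on abundant genes. Testing against a 1.5-fold change left 521 higher and 588 lower, because the null is wider, and an adjusted p under 0.01 left 1210 higher. A t reference with 3 degrees of freedom left 0 and 0 (2513 genes at an unadjusted p under 0.05, smallest adjusted p 0.37), because its wider tails give the same statistics larger p-values. Recentring on the secreted plasma proteins gave 5513 and 944 by construction, since it shifts every gene by 0.48. It also gave Hhex 1.03 (adjusted p = 0.0084), past the threshold, against 0.24 to 1 under the other alternatives, and the values not past the test of Cdkn1a (0.19), H19 (0.19), Krt8 (0.47) and Krt18 (0.024) changed sign, as did Alb (-0.0469) after recentring on abundant genes. With the log2 fold change as statistic 5 lists were higher and 6 lower, and the cause was not tested; other list settings gave 13 to 19 higher and 9 to 12 lower. Chromosomes had 0 calls under each alternative tried. After recentring on the secreted proteins the macrophage, unfolded protein, Nrf2, immediate early and ribosomal protein lists passed as higher, and the transcription factor and respiratory chain lists no longer passed. Of the named genes, 180 lost their call with the t reference, 81 against 1.5-fold, 16 at 0.01 and 20 after recentring on the secreted proteins. Low counts limit the rest: genes with a mean under 50 had a median standard error of 1.62.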

Other observations

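The tests below were chosen after the data were seen, except the tests of fasting and feeding genes and of low counts among pseudogenes. Gene families defined by symbol extend the picture of the lists, whose members they partly share. Of 76 cytochrome P450 genes, 40 were lower and 4 higher (Fisher's exact test of the split against all other called genes, adjusted p over 20 families = 4.2e-08). UDP-glucuronosyltransferase genes, which conjugate drugs and bilirubin, had 10 lower and 0 higher of 18 (adjusted p = 0.0045), sulfotransferase genes 10 lower and 1 higher of 17 (adjusted p = 0.016), and carboxylesterase genes 8 lower and 0 higher of 16 (adjusted p = 0.012). Kinesin genes, motors that include many of mitosis, had 13 higher and 1 lower of 35 (adjusted p = 0.0097), and histone cluster genes 20 higher and 0 lower of 50 (adjusted p = 2.2e-05). Collagen genes (10 higher, 2 lower of 40, adjusted p = 0.099), Serpina genes (2 higher, 9 lower of 25, adjusted p = 0.094), chemokine genes (0 higher, 4 lower of 23, adjusted p = 0.12), glutathione S-transferase genes (3 higher, 5 lower of 21, adjusted p = 0.71) and MHC genes (3 higher, 5 lower of 31, adjusted p = 0.71) did not pass. Nor did the remaining 9 families.

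Called genes on the X chromosome were split 71 higher to 32 lower, against 1828 to 1705 in all (Fisher's exact odds ratio 2.11, adjusted p over 21 chromosomes = 0.0087). The odds ratio was 1.87 (65 higher, 41 lower, Fisher's exact p = 0.0021) after recentring on abundant genes and 1.39 (185 higher, 23 lower, Fisher's exact p = 0.16) after recentring on the secreted plasma proteins, where the split no longer passed. No other chromosome passed, with chromosome 13 next (47 higher, 72 lower, adjusted p = 0.071). The 4 Y-linked genes had standard errors of 2.71 to 2.91. Whether the sex of the embryos bears on the X split was not tested. The median of abundant X-linked genes was 0.03, so the split concerned the called genes, not the chromosome as a whole.

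Genes that hepatocytes raise around and after birth were lower in 4N liver. A smaller share of hepatocyte RNA in the 4N libraries, as the only cause, is argued against by the secreted plasma proteins. Their median exceeded that of the maturation list by 2.40 on the log2 scale (permutation p = 1.6e-04), a gap already seen when the test was chosen. The secreted list itself fell (median -0.48, 13 lower and 1 higher of 27), so a smaller share as part of the cause is not excluded. For a fasting or hormonal state of the WT livers, the prediction was a fasting-induced median below -0.5 and a feeding-induced one above 0.5. Either median on the other side of 0 would go against it. The 15 fasting-induced genes, listed before their values were seen, had a median of 0.30 (interval -0.46 to 0.73), members going both ways. The 13 feeding-induced genes had one of 0.49 (interval 0.0061 to 1.37). By the prediction the fasting median goes against this state. Its interval, not part of the prediction, includes 0 and the feeding genes lean as predicted. Lists outside the prediction also moved as such a state would. PPAR alpha targets and fatty acid oxidation genes had a median of -0.90 (16 lower and 1 higher of 21). Fatty acid synthesis genes had one of 1.46 (10 higher and 2 lower of 17). The state is therefore not excluded. A difference in developmental stage cannot be told apart from ploidy, since all embryos that received tetraploid cells are in 1 group. The fetal hepatoblast median of 0.58 would follow from either.

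Erythroid genes were higher in 4N liver. A lower share of hepatocytes, as the only cause, would raise every other cell type alike, but the erythroid median exceeded the endothelial one by 1.66 (permutation p = 1e-05, the smallest these permutations can give). The medians of 1.56 and -0.10 were already seen when this test was chosen, so its p-value adds little to them. More erythroid RNA in general stays open, since the 20 of 21 adult-type members that rose are the pattern itself and cannot decide it. In the authors' deposited table, the 3 embryonic globins lay above the median of the adult-type members (SD 0.63). The gap was 1.97 for Hbb-bh1 (SE 0.69), 5.54 for Hba-x, their median, and 8.73 for Hbb-y, whose fitted WT mean was only 1.05. Hbb-bh1 does not stand apart, since the adult-type Hba-a2 rose about as much (3.29, SE 0.34). An even rise does not account for Hba-x and Hbb-y. Both were scarce, with means over all libraries of 488 and 778, against 785145 for the adult Hbb-bs. Their standard errors were wide, at 1.604 and 1.496. Earlier erythroid cells may be present. Whether this reflects ploidy, stage, the injected cells or the host genotype was not tested.

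Pseudogenes were over-represented among the large differences. Of called genes with an absolute log2 fold change of at least 4, 16.6% were pseudogenes, against 3.94% of other called genes (Fisher's exact odds ratio 4.84, p = 3.9e-22). Low counts do not account for this, since the Fisher's exact odds ratio was 10.6 (p = 2.4e-12) among genes with a mean of at least 300, where 15 of the 20 pseudogenes were lower. A genetic background difference between the injected cells and the WT embryos, with reads shared between near-identical copies, may be a candidate explanation that the first odds ratio, being the pattern itself, cannot decide, and it would also affect Rps2 and, singled out after their values were seen, Rps3a2 and Rps26-ps1. The strains are not given in the sources used here, and a difference in read processing between groups was not tested.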
